A study of Mus musculus with 4 samples.

How the data were processed

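The series holds 4 single-cell RNA libraries from orthotopic mouse pancreatic tumours grown from 2 KPC lines, with 1 sorted (enriched) and 1 unsorted (whole) library per line. Each library is a matrix of UMI counts per gene and droplet barcode as the authors deposited it, made with 5' chemistry and not normalized. Reads were aligned to mm10 and counted with Cell Ranger 6.1.1, per the submitters' processing notes, while the software entry reads Cell Ranger 4, per the file headers. The tumours were dissociated on day 13, and cells negative for CD45, CD31, EPCAM and TER119 were sorted for the enriched libraries, per the labels' protocols. The matrices list 32285 genes and 624722 (enriched KPC-4545), 270479 (whole KPC-4545), 497319 (enriched KPC-3403) and 342947 (whole KPC-3403) barcodes, so cells had to be called here. Gene positions are those of the mm10 annotation used here.

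Cells needed at least 500 UMIs, 250 genes and at most 20% mitochondrial UMIs. Barcodes of up to 5000 UMIs also had to differ from the profile of barcodes with at most 100 UMIs in a Monte Carlo test with a Dirichlet-multinomial (1000 draws, false discovery rate 0.01). Of 3482, 880, 3118 and 1925 barcodes with 500 UMIs, in the same order of libraries, 566, 333, 330 and 681 had too few genes. Over the mitochondrial limit were 1760, 28, 504 and 62, some of them also with too few genes. Of the rest, 38, 7, 47 and 97 resembled free RNA, and 22, 2, 51 and 10 were removed as doublets by Scrublet scores, at the expected number of 0.8% per 1000 cells. Cells held 64.8%, 58.5%, 82.8% and 65.1% of UMIs. The enriched libraries had the deeper cells, and all values of the whole KPC-4545 fibroblast-like cells rest on 3 cells. In scanpy 1.11.5, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1 gave 31 clusters. A cluster took the class with the highest marker score among 18 classes with at least 3 markers detected in 10% of its cells, and 7 clusters with 2063 cells stayed unnamed. Fibroblast-like cells were clustered again with 20 components and named by 3 state lists. The scoring details were not fixed in advance: 3 naming rules were tried after clusters and library makeup had been seen, and the rule kept was chosen after its cell counts and stability over settings had been seen. The doublet rule and the dispersion of the free RNA test were also set after their results had been seen.

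Samples were grouped by the labels. The cell thresholds, marker lists, 14 gene lists, tests and named-gene rule were fixed before the data were examined. Shares have exact Clopper-Pearson 95% intervals and a two-sided exact permutation test of 2 against 2 libraries, with a smallest possible p of 0.333. UMI counts summed over cells of a library were tested with edgeR 4.0.16 (glmQLFit, robust; TMM; filterByExpr; Benjamini-Hochberg at 0.05; R 4.3.3) with the line as a term, which leaves 1 residual degree of freedom, and with DESeq2 1.42.0 as an alternative. Replicate numbers pair the libraries, since each number is 1 tumour line; in a check over 8542 genes the deviations of the KPC-4545 libraries from their preparation means correlated at 0.262. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), camera with an estimated correlation, and fry. The preset correlation is assumed. The estimated one rests on 1 residual degree of freedom, so that version could hardly pass any list and its failures decide little. The lists were immediate early response, heat shock, extracellular matrix, matrix proteases and inhibitors, chemokines and cytokines, MHC class II, interferon response, TGF-beta response, hypoxia and glycolysis, proliferation, mitochondrially encoded mRNA, complement, mesenchymal transition, and epithelial junction and keratin.

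The fibroblast test could not be run as designed. A class needed 20 cells in a library, the whole KPC-4545 library had 3 fibroblast-like cells, and 3 libraries leave the additive fit no residual degree of freedom. Fibroblast differences are therefore values of 1 library against 1, from TMM-scaled sums with 0.5 UMIs added for log2 values, with exact counting intervals. List medians are given as percentiles of 10000 random lists drawn from 20 bins of expression, for genes with a mean of at least 1 CPM. A fold against 0 UMIs is a lower bound against a floor of 3 UMIs in that library.

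Named genes are the sort targets; per test, up to 10 genes per direction with the largest log2 change among those passing, with a mean of at least 10 CPM and the same direction in both lines, or, if none pass, the 5 with the smallest p, named as not passing; and per list up to 4 passing members or else the 2 with the highest mean CPM. For fibroblasts, where the designed test could not be run, the 10 genes per direction with the largest value of the counting bound nearest to no difference were taken, an adaptation made after the data had been seen. Genes that lead a cluster, and further list members given as examples, were chosen after their values were seen. Unnamed gene models are counted only, and a few genes that the rule names are not reported here.

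The steps were tested on simulated data. The free RNA test called 99.5% to 100% of 200 simulated cells and at most 0.5% of 200 empty barcodes. The edgeR fit recovered 99% of genes changed by log2 2 and 28% of those changed by log2 1 for all cells (15337 genes), 99% and 22% for epithelial cells (11994 genes), and 64% and 9.09% for the fibroblast fit of 3 libraries (7461 genes). Of its 136, 129 and 75 calls, 9, 8 and 2 were of unchanged genes. The simulated counts had a dispersion of 0.05 and no difference between the lines. The recovery therefore does not hold for genes that vary more, as the sort targets did here. Alternatives changed the cell thresholds, doublet and free RNA steps, clustering, naming, size factors, filter, test, line block and libraries, and in fibroblasts also depth, number of cells and free RNA.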

Results

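Droplet single-cell RNA sequencing was used to compare 2 ways of preparing mouse pancreatic tumours for the study of cancer-associated fibroblasts, the collagen-producing stromal cells of a tumour. The tumours were grown in the pancreas of C57BL/6J mice from KPC cells, a mouse model of pancreatic cancer, and were collected on day 13. There were 4 libraries, 2 per preparation. The lines KPC-4545 (replicate 1) and KPC-3403 (replicate 2) each gave 1 library of the unsorted suspension, called whole, and 1 of cells sorted as negative for CD45, CD31, EPCAM and TER119, called enriched. These antigens mark leukocytes, endothelial, epithelial and erythroid cells. The enriched libraries held 47207893 UMIs (KPC-4545) and 51450719 UMIs (KPC-3403), and the whole libraries 5746733 and 13990046 UMIs. After filtering, 1632 and 2477 cells remained in the enriched libraries, and 527 and 1110 cells in the whole libraries, in the same order of lines. The median UMIs per cell were 8481 and 16262 in the enriched libraries and 3589 and 4047.5 in the whole libraries. The labels do not say whether libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical in part. The libraries of 1 preparation are of different lines, so the spread in the permutation test includes the difference between lines. In fits with a line term it is how far the preparation difference varies between the lines.

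The first question was how far the sort raised the share of fibroblasts. Fibroblast-like cells, which express the collagen genes Col1a1 and Col3a1 and the proteoglycan gene Dcn, made up 22.8% of cells (95% exact Clopper-Pearson interval 21.1 to 24.5, 564 cells) in the enriched KPC-3403 library and 3.78% (2.74 to 5.08, 42 cells) in the whole KPC-3403 library, a 6.02-fold ratio. In KPC-4545 they made up 2.94% (2.18 to 3.88, 48 cells) of the enriched library and 0.569% (0.118 to 1.65, 3 cells) of the whole library, a 5.17-fold ratio. The enriched libraries averaged 12.9% and the whole libraries 2.18%, a difference of 10.7 percentage points (n = 2 per preparation; two-sided exact permutation p = 0.667). With 2 libraries against 2 the smallest possible p is 0.333, so no share could pass 0.05. The intervals cover counting error only. The mean difference was 20.6 percentage points without the enriched KPC-4545 library and 0.765 without the enriched KPC-3403 library. It was 17.4 percentage points with a finer clustering (Leiden resolution 2) and 27.6 when nearly tied clusters were named by the share of markers found.

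A large stromal cluster (cluster 0, 780 cells, 764 of them from the enriched KPC-3403 library) carried Dcn and Pdgfra beside the mesothelial gene Wt1 and remained unnamed. Cells in unnamed clusters nearest to mesothelial cells were 30.8% of the enriched KPC-3403 library, 0.811% of the whole KPC-3403 library, 0.184% of the enriched KPC-4545 library and 0.759% of the whole KPC-4545 library. Mesothelial-like cells, the lining of the abdominal cavity, were 12.5% and 0.306% of the enriched KPC-3403 and KPC-4545 libraries and 0.450% and 0.759% of the whole libraries (exact permutation p = 1, n = 2 per preparation), and their mean difference was -0.298 percentage points without the enriched KPC-3403 library. Fibroblast-like, mesothelial-like and these unnamed clusters together held 66.1% of the enriched and 5.05% of the whole KPC-3403 library, and 3.43% and 2.09% of the KPC-4545 libraries. Unnamed clusters nearest to epithelial cells held 64.0% of the enriched KPC-4545 library, against 5.12% of the whole KPC-4545, 2.38% of the enriched KPC-3403 and 13.7% of the whole KPC-3403 library.

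**Figure D1:**
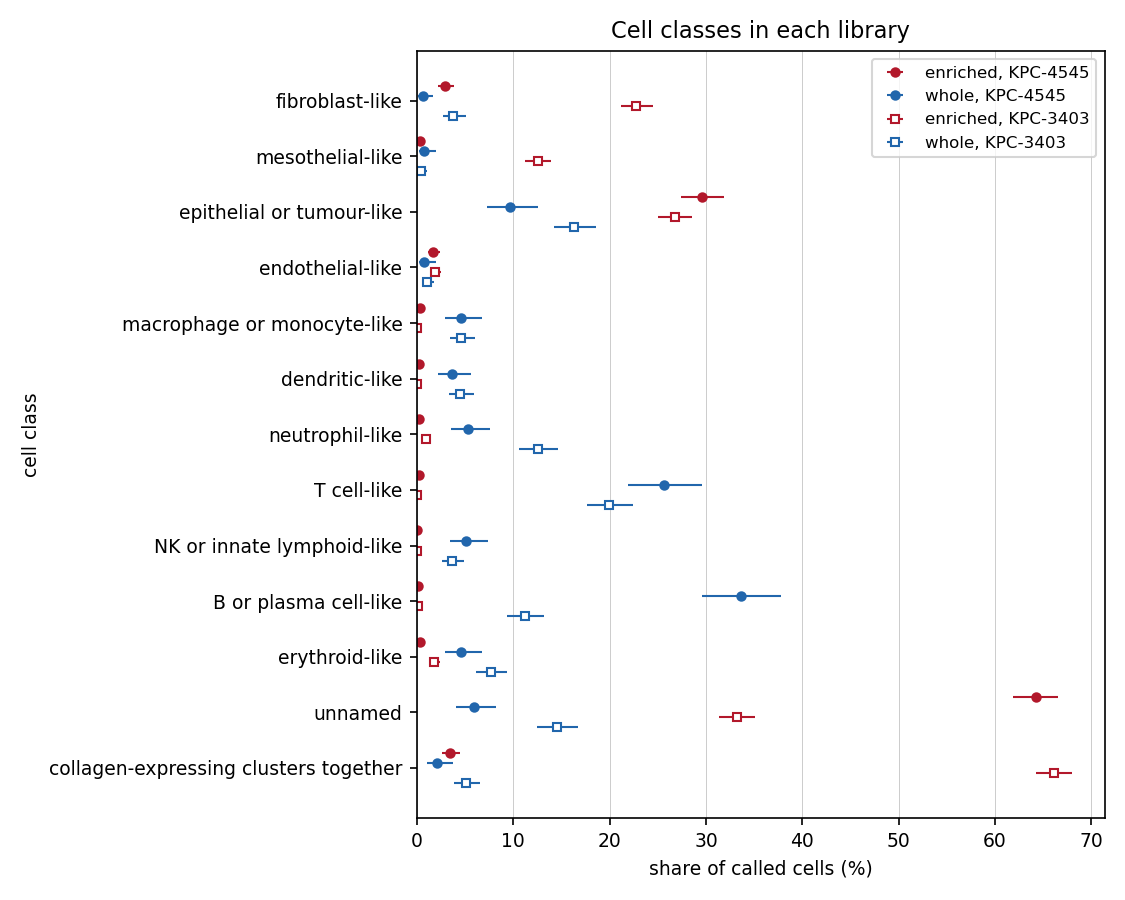
Share of called cells (%) in each cell class, per library. Points are shares, bars are exact Clopper-Pearson 95% intervals, red is enriched and blue is whole, filled circles are KPC-4545 and open squares KPC-3403; fibroblast-like cells reach 22.8% in the enriched KPC-3403 library and 2.94% in the enriched KPC-4545 library.

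The other classes show which cells the sort removed. T cells, B or plasma cells and other immune classes together were 77.8% (KPC-4545) and 56.3% (KPC-3403) of the whole libraries and 0.980% and 1.05% of the enriched libraries. B or plasma-like cells were 33.6% and 11.2% of the whole libraries and 0.0613% and 0.0807% of the enriched ones, and T-like cells were 25.6% and 19.9% against 0.184% and 0 of 2477 cells, which allows a share of up to 0.121% (3 cells; upper limit of the exact interval 0.149%). NK-like cells were 5.12% and 3.60% of the whole libraries, with 0 cells in the enriched libraries, which allows up to 0.184% in KPC-4545 (exact limit 0.226%). Macrophage-like cells were 4.55% and 4.59% against 0.306% and 0.0404%, dendritic-like cells 3.61% and 4.50% against 0.184% and 0.0404%, and neutrophil-like cells 5.31% and 12.5% against 0.245% and 0.888%. Erythroid-like cells were 4.55% and 7.66% against 0.306% and 1.78%. In KPC-3403, cluster 23 of this class held 40 enriched and 23 whole cells (1.61% and 2.07% of the libraries). Clusters 28 and 29 held 4 and 0 enriched against 34 and 28 whole KPC-3403 cells. Hbb-bs stood at 182 UMIs per 10000 in cluster 23 and at 3208 and 4673 in clusters 28 and 29. Epithelial or tumour-like cells, which the EPCAM gate was set to exclude, were instead 29.6% and 26.8% of the enriched libraries against 9.68% and 16.3% of the whole libraries. The unnamed clusters nearest to epithelial cells held another 2.38% of the enriched and 13.7% of the whole KPC-3403 library. Counted together with them, the enriched KPC-3403 library no longer held the larger share. In KPC-4545 these clusters held 64.0% and 5.12%, so the direction stayed. Cells of cluster 19, named endothelial-like by genes such as Plvap and Egfl7, were 1.65% and 1.90% against 0.759% and 0.991%, but -0.381 percentage points apart on average (other cell class shares, endothelial) with at least 1000 UMIs and 500 genes per cell. The enriched cells of this cluster held 0 (KPC-4545) and 1 UMI (KPC-3403, 0.0622 per 10000) of Pecam1 against 4.68 per 10000 in its cells of the whole KPC-3403 library, and Dcn and Col3a1 were found in 68.5% and 69.7% of its cells, so its share is not a measure of endothelial cells alone. In each of these classes, as named, both lines lay on the same side, and the exact permutation p was 0.333, the smallest possible. Shares of one library depend on each other, since the removal of immune cells raises the share of what remains.

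Transcripts of the sorted antigens were read in the sums over all cells. Ptprc, which encodes CD45 (ENSMUSG00000026395, mm10 chromosome 1, 138062861 to 138175708), reached 255 and 142 CPM in the whole KPC-4545 and KPC-3403 libraries and 0.0654 (2 UMIs) and 0.587 CPM (25 UMIs) in the enriched ones, ratios of 3901 (1077 to 32266) and 242 (163 to 375). Pecam1, which encodes CD31 (ENSMUSG00000020717, chromosome 11, 106654217 to 106750628), reached 37.8 and 16.5 CPM against 0.359 and 0.963. Epcam (ENSMUSG00000045394, chromosome 17, 87635979 to 87651129) reached 146 and 287 CPM against 1.34 and 11.0. The haemoglobin gene Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096) reached 23204 and 15147 CPM against 3.63 and 32.8. In the edgeR fit with the line as a term the log2 differences were -9.34 for Ptprc (SE 1.33, adjusted p = 0.123), -5.31 for Pecam1 (adjusted p = 0.146), -5.70 for Epcam (adjusted p = 0.119) and -10.73 for Hbb-bs (adjusted p = 0.131). Hbb-bt, Hba-a1 and Hba-a2, the other haemoglobin genes, had log2 differences of -9.73, -9.74 and -10.46 (edgeR adjusted p = 0.0854, 0.0949 and 0.123). None of these genes passed, with the line term or without it. Each passed with DESeq2, and each passed without the enriched KPC-4545 or KPC-3403 library, in fits that also dropped the line term and had 1 enriched library.

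Across all 15101 genes tested in these sums, edgeR found 40 genes lower in the enriched libraries and 0 higher, with 2533 genes at an unadjusted p under 0.05. The 10 genes named by the rule fell in both lines, with 0 to 2 UMIs in each enriched library, so their fitted log2 values depend on the prior count. Camp, a neutrophil granule peptide, had 0 UMIs in the enriched KPC-4545 library against 3335 in the whole one (at least 10121-fold lower at 3 UMIs in that library, exact lower limit 8227) and 1 against 8325 in KPC-3403 (ratio 38940, 6987 to 1.5e+06). Chil3, a myeloid chitinase-like gene, had 1 against 879 (8003, 1433 to 316451) and 2 against 1068 (2498, 690 to 20651). The fitted values were -15.60 and -11.86 for these 2. They were -13.47, -10.87 and -11.62 for the cytotoxic lymphocyte genes Gzma, Klrk1 and Cd8a. The T cell genes Ctla4, Ms4a4b, Sh2d2a, Il2rb and P2ry10 had -11.71, -12.41, -11.16, -10.45 and -10.40 (all 10 adjusted p from 0.0427 to 0.0486 by edgeR). For the last 8 genes the lower limits of the counting ratios per line lay between 218 (P2ry10, KPC-3403) and 1978 (Gzma, KPC-3403). The genes with the smallest unadjusted p among those higher in the enriched libraries did not pass in edgeR: the small heat shock gene Hspb1 (log2 3.40, adjusted p = 0.0596), the chemokine genes Cxcl1 (3.41) and Ccl2 (3.43), the adhesion gene Vcam1 (3.79) and the lipocalin gene Apod (5.98, adjusted p = 0.0692). The Apod value was 1.99 without the enriched and 12.65 without the whole KPC-3403 library, in fits that also dropped the line term. The count in this fit of the sort target genes and all others was 26 with RLE size factors, 774 without a filter, and 1611 with DESeq2, of which 299 were higher. It was 32 without the line term. Fits that left out a library also had to drop the line term, and their counts were 1491 (no enriched KPC-4545), 2700 (no enriched KPC-3403) and 0 (either whole library left out).

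Among the fixed gene lists in these sums, all 22 immediate early genes, all 13 heat shock genes and all 12 mesenchymal transition genes were higher in the enriched libraries, and 0 of 18 epithelial junction genes and 0 of 7 MHC class II genes were. No list member passed over all genes by edgeR. Adjusted over the list alone, 19 immediate early, 10 heat shock, 7 chemokine, 4 mesenchymal transition and 2 protease genes were higher and 11 epithelial junction genes lower, and interferon response (2 higher, 1 lower) and mitochondrially encoded genes (1 higher, 1 lower) went both ways. The epithelial junction list holds Epcam, an antigen of the gate. Without Epcam 8 of its 17 genes were lower over the list alone (camera adjusted p = 1.7e-07, and adjusted p = 0.517 with an estimated correlation). By camera, immediate early (adjusted p = 7.9e-10), chemokine (15 of 16 higher, 1.6e-08), heat shock (1.7e-07), mesenchymal transition (7.4e-05), extracellular matrix (17 of 20, 0.00243) and protease genes (13 of 15, 0.00243) lay higher, and epithelial junction (1.6e-08) and MHC class II genes (0.00574) lower. None held with an estimated correlation (camera adjusted p = 0.517 with an estimated correlation for immediate early, chemokine, mesenchymal transition and epithelial junction genes, 0.578 for heat shock, 0.80 for proteases and MHC class II, and 0.864 for extracellular matrix). That version rests on 1 residual degree of freedom. For chemokine genes its correlation was -0.05, below the preset 0.01, and its unadjusted camera p was still 0.0996. TGF-beta response (8 of 12 higher, camera adjusted p = 0.0696), complement (7 of 8, 0.353), proliferation (12 of 20, 0.499), hypoxia (9 of 15, 0.561), interferon (11 of 22, 0.561; median and mean -0.04, direction up) and mitochondrially encoded genes (3 of 13, 0.573) did not pass. These sums mix classes whose shares differ between the preparations, and how much of each list's difference that brings was not tested.

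Sequencing depth per fibroblast-like cell did not separate the preparations. The median was 7402.5 UMIs (enriched KPC-4545), 8996 (whole KPC-4545, 3 cells), 12352.5 (enriched KPC-3403) and 12230.5 (whole KPC-3403), a mean of 9877.5 against 10613 (two-sided exact permutation p = 1, n = 2 per preparation). The median genes per cell were 2352, 3030, 3078.5 and 3285. With each cell thinned to 1000 UMIs, which left out 2, 0, 3 and 0 cells, the medians were 597.5, 579, 583 and 589 genes (exact permutation p = 0.667), and genes per fibroblast at a fixed number of UMIs turned to a mean difference of -34.5 when cells were thinned to 2000 UMIs. The difference in median UMIs turned to 1739 without the enriched KPC-4545 library and to 881.5 without the whole KPC-3403 library, and was -2353 without the whole KPC-4545 and -3211 without the enriched KPC-3403 library.

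Fibroblasts of this tumour are described as myofibroblastic, inflammatory or antigen-presenting, and the next question was whether the sort changed their shares. The shares cover fibroblast-like cells only and leave out the unnamed stromal cluster, with 764 cells of the enriched KPC-3403 library. That cluster held more Cd74, Saa3 and Slpi, markers of the antigen-presenting list, per UMI than the fibroblast-like cells of that library. In KPC-3403 the inflammatory-like state, with genes such as Clec3b, Ly6c1 and Scara5, held 40.8% of fibroblast-like cells in the enriched library (230 of 564) and 23.8% in the whole library (10 of 42). Those genes led sub-cluster 0, with 114 of the 230 enriched and 3 of the 10 whole cells. Sub-cluster 8 of this state, led by Cfd and Fabp4, held 22 and 6 of them. The myofibroblastic-like state, named by a list that includes the contractile gene Acta2, held 26.1% of enriched and 42.9% of whole KPC-3403 fibroblast-like cells. The antigen-presenting-like state held 20.0% and 28.6%. In the enriched KPC-4545 library these states held 47.9% (inflammatory), 43.8% (myofibroblastic) and 4.17% (antigen-presenting) of 48 cells, and the whole KPC-4545 library had only 3 fibroblast-like cells. Of the 21 myofibroblastic-like cells of the enriched KPC-4545 library 16 lay in sub-cluster 9, against 6 of the 564 enriched KPC-3403 cells. It is led by Kcnq1ot1, mt-Atp8 and Neat1, with no myofibroblastic marker among its 10 leading genes and a median of 3951 UMIs. The mean inflammatory difference (fibroblast state shares, inflammatory) was 32.4 percentage points, with 0 of 3 cells in the whole KPC-4545 library (0 to 70.8%). It was 20.5 without that library and turned to -1.67 at Leiden resolution 2. The myofibroblastic difference was -19.9, and -7.95 without that library. The exact permutation p was 0.333 for the inflammatory, 0.667 for the myofibroblastic and 1 for the antigen-presenting state (n = 2 per preparation). Hypoxia genes (Ndufa4l2, Car9 and Egln3) led 1 antigen-presenting-like sub-cluster, which held 12 of the 42 whole and 52 of the 564 enriched KPC-3403 cells. It held every antigen-presenting-like cell of the whole library, with no marker of that state among its 10 leading genes. The other such sub-cluster, with the marker Slpi among them, held 0 whole and 61 enriched KPC-3403 cells. Cycling genes such as Birc5 and Ube2c led 1 myofibroblastic-like sub-cluster, which held 16 whole and 85 enriched KPC-3403 cells. It too has no marker of its state among its 10 leading genes. A myofibroblastic-like sub-cluster with the marker Lrrc15 among them held 0 whole and 56 enriched KPC-3403 cells. The antigen-presenting difference was -16.5 percentage points without the whole KPC-4545 library, 12.1 without the whole KPC-3403 library, 5.75 without the enriched KPC-4545 library and -10.1 without the enriched KPC-3403 library, against -2.18 with all 4.

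Within fibroblast-like cells, expression could be set side by side for the 2 preparations only in KPC-3403, because the whole KPC-4545 library had 3 such cells. These are values of 1 library against 1, with no replicate check and no p-value, and the intervals cover counting error only. Stress genes were higher in the enriched library: all 13 heat shock genes, with a median log2 difference of 1.04 (0.97 to 1.23; above all 10000 random lists matched on expression, percentile 100), and 20 of 22 immediate early genes, with a median of 0.53 (0.44 to 0.58; percentile 100). The chaperone gene Hspa8 was 2.03-fold (1.88 to 2.19) and Hsp90ab1 1.08-fold (1.01 to 1.15) higher, and the early transcription factor genes Jun and Fos 1.52-fold (1.42 to 1.63) and 1.15-fold (1.09 to 1.22). Hypoxia and glycolysis genes were lower, in 14 of 15 members, with a median of -1.39 (-1.58 to -1.30; percentile 0). Among them, Gapdh and Ldha reached 938 and 758 CPM against 2997 and 1386 CPM. The sub-cluster led by hypoxia genes held a larger share of the whole library, 12 of 42 cells against 52 of 564.

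Chemokine and cytokine genes had a median of 0.27 (percentile 97.6; 0.25 with the gene at 0 UMIs set to the floor of 3 UMIs), with Ccl7, a monocyte chemoattractant, 4.12-fold (3.66 to 4.66) and Cxcl1 1.85-fold (1.69 to 2.02) higher. Matrix proteases and inhibitors had a median of 0.44 (percentile 99.9), although the 2 most abundant members, the inhibitor genes Timp1 and Timp3, had log2 differences of -0.47 and -0.52. Extracellular matrix genes stood at 0.13 (percentile 81.3), with Sparc 1.25-fold (1.22 to 1.29) and Col3a1 1.12-fold (1.09 to 1.14) higher. TGF-beta response genes had a median of -0.30 (percentile 2.02), with Pmepa1 at 366 against 484 CPM. MHC class II genes had a median of 0.52 (5 of 6 higher, percentile 99.2), with Cd74, the invariant chain, 2.74-fold (2.19 to 3.48) and H2-Ab1 1.02-fold (0.783 to 1.35). That median turned to -0.17 after free RNA was subtracted and to -0.69 with equal numbers of cells. The share subtracted from the enriched library, an estimated 9.60% of UMIs, is probably too high, by the erythroid marker values given below. Proliferation genes had a median of 0.66 (percentile 100), but Pcna and Tyms, the most abundant members, had log2 differences of -0.36 and -0.67, and the median turned to -1.40 with equal numbers of cells and to -0.60 in thinned cells. Complement genes stood at 0.21 (percentile 85.7; C3 1.14-fold, Serping1 1.28-fold), interferon response genes at -0.17 (percentile 11.0; Ifitm3 log2 0.35, B2m -0.42), mitochondrially encoded genes at -0.15 (percentile 5.09; mt-Co1 -0.19, mt-Atp6 0.07), and mesenchymal transition genes at -0.06 (percentile 31.9; Vim 0.43). Epithelial junction and keratin genes stood at -0.57 (percentile 8.30; Krt19 -3.56, Tjp1 -0.28), and epithelial marker UMIs made up 0.0144% of UMIs in enriched and 0.0216% in whole KPC-3403 fibroblast-like cells.

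Single genes were named by the bound of the counting interval nearest to no difference. The lipocalin gene Apod was 21.9-fold higher in the enriched library (11.1 to 50.7), the Wnt modulator gene Sfrp4 9.98-fold (7.40 to 13.8), the growth factor gene Ptn 15.3-fold (6.99 to 41.7), Ace 25.3-fold (8.62 to 123), and Dlk1 61.4-fold (11.0 to 2429, with 1 UMI in the whole library). Against 0 UMIs in the whole library, taken as a floor of 3 UMIs in that library, Cxcl13, a B cell chemoattractant, was at least 38.9-fold higher (lower limit of the exact counting interval 31.6), C1qtnf3 at least 22.9-fold (18.6), the complement factor gene Cfd at least 17.2-fold (14.0), Angptl1 at least 12.3-fold (9.99) and Rrad at least 8.19-fold (6.62). Cxcl13 leads the large unnamed stromal cluster of that library, free RNA made up an estimated 9.60% of UMIs in its fibroblast-like cells against 0.420% in the whole library, and the Cxcl13 log2 difference turned negative after free RNA was subtracted. The genes lower in the enriched library included Hbb-bs (inverse fold 211, 78.8 to 795), Hba-a1 (193, 49.2 to 1660.0, 2 UMIs) and Hba-a2 (410, 68.7 to 16648, 1 UMI), with erythroid marker UMIs at 0.0232% in whole and 0.000531% in enriched fibroblast-like cells. They also included the progesterone receptor gene Pgr (181, 45.9 to 1560), Gipr (43.7, 19.5 to 111), Cd52 (32.1), Greb1 (24.1), Ptpn5 (20.4), Krt7 (16.9, 8.29 to 35.2) and Hoxd11 (0 against 14 UMIs, at least 56.2-fold lower against the floor of 3 UMIs, exact lower limit 40.0). The Krt7 log2 difference turned to 2.32 with a minimum of 1000 UMIs and 500 genes per cell.

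A test across preparations needed both enriched libraries against 1 whole library without a line term. It called 125 genes by edgeR, 54 higher and 71 lower (29 with DESeq2, 12 in thinned cells, 62 at Leiden resolution 2, 70 when near ties were named by markers found), and its lone whole library is assumed to vary like the enriched ones. With all 4 libraries and the line as a block it called 31. The values in the rest of this paragraph are of the fit of 3 libraries without a line term. In this fit 4 heat shock genes passed over all genes and 8 adjusted over the list alone, and 8 hypoxia genes were lower over all genes and 12 adjusted over the list alone. By camera with its preset correlation, heat shock (adjusted p = 2.9e-16), proliferation (0.000131), chemokines (0.00497), immediate early genes (0.0284) and proteases (0.0295) lay higher, and hypoxia (2.2e-24) and epithelial junction genes (1.05e-06) lower. None held with an estimated correlation (adjusted p = 0.686 with an estimated correlation, 0.816 for immediate early genes). For MHC class II the median (0.40) and mean (0.13) were positive and the direction by camera was down (adjusted p = 0.193 by camera), for mesenchymal transition genes the mean was 0.00285 with direction down, and for mitochondrially encoded genes the median was -0.05 and the mean 0.17 with direction up.

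**Figure D2:**
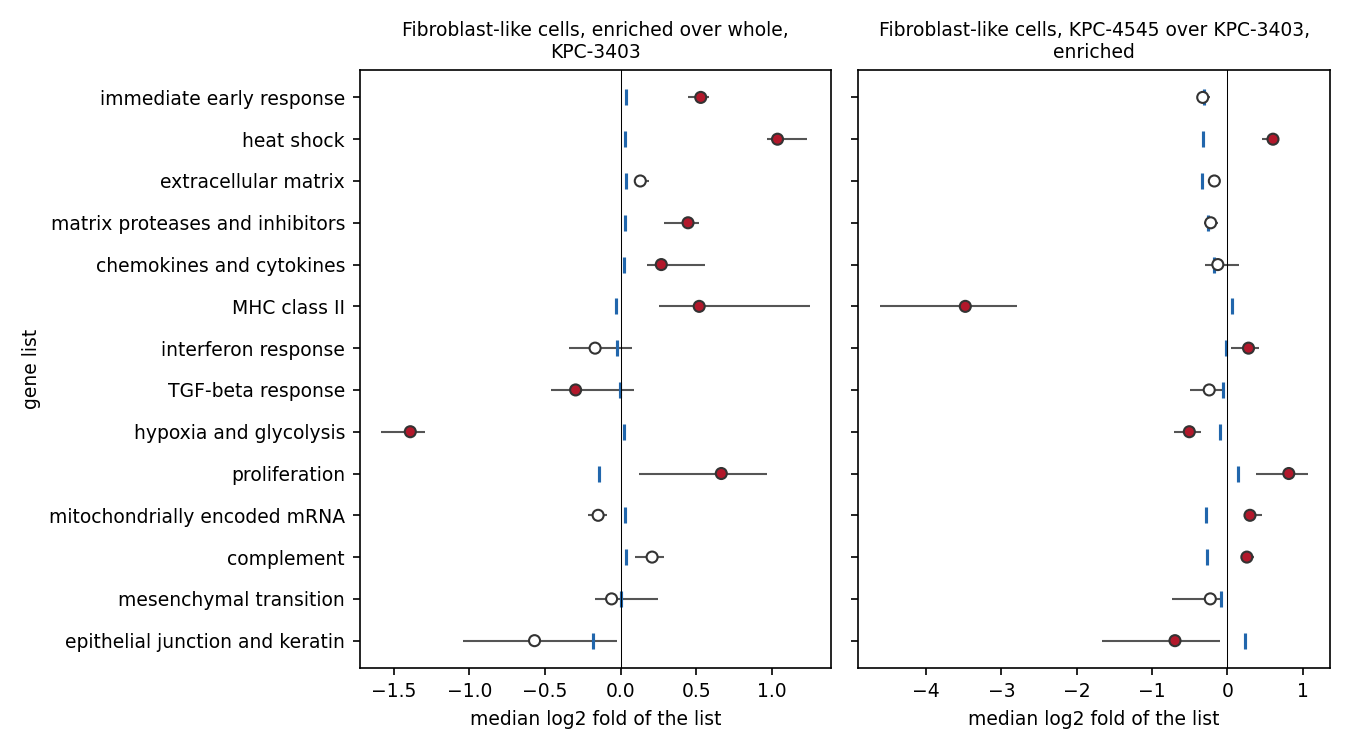
Median log2 fold difference per gene list in fibroblast-like cells: enriched over whole in KPC-3403 (left) and KPC-4545 over KPC-3403 in the enriched libraries (right). Bars are 95% counting intervals, blue ticks are medians of random lists matched on expression, and filled red points lie outside the central 95% of these; heat shock genes stand at 1.04 and 0.60, and MHC class II genes at 0.52 and -3.48.

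The second factor of the design was the tumour line, compared in fibroblast-like cells of the enriched libraries (48 cells of KPC-4545, 564 of KPC-3403), again as values of 1 library against 1. Fibroblast-like cells of KPC-4545 tumours held fewer MHC class II transcripts: 0 of 6 genes were higher, with a median of -3.48 (-4.61 to -2.79; percentile 0), or -3.19 with the gene at 0 UMIs set to the floor of 3 UMIs. Cd74 reached 13.5 CPM against 356 CPM (inverse fold 26.3, 12.8 to 65.5) and H2-Ab1 5.80 against 102 CPM (17.6, 5.99 to 85.5). The antigen-presenting-like state held 2 of the 48 and 113 of the 564 cells, and free RNA an estimated 2.48% and 9.60% of UMIs. Both free RNA shares are probably too high. In KPC-4545, 93 of the 99 marker UMIs behind the estimate were neutrophil markers. Erythroid markers had 0 UMIs in these KPC-4545 cells (upper exact limit 0.00076%), against 0.706% of UMIs in that library's free RNA. The median (fibroblasts, KPC-4545 against KPC-3403, list MHC class II) was -3.52 after free RNA was subtracted, -2.21 in thinned cells, -1.75 with equal numbers of cells and -2.15 when near ties were named by markers found. Proliferation genes were higher in 17 of 20, with a median of 0.81 (percentile 99.99), as in Mki67 (5.19-fold, 3.50 to 7.56) and Tyms (2.58-fold, 1.77 to 3.68), but the median was -0.24 when near ties were named by markers found. Heat shock genes were higher in 13 of 13 (median 0.60, percentile 100; Hspa8 1.23-fold, Hspb1 1.06-fold). Random lists of abundant genes had medians of about -0.3 here (-0.34 to 0.23 over the 14 lists), so medians are read against them.

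Mitochondrially encoded genes had a median of 0.30 (percentile 99.8; mt-Co1 log2 0.22, mt-Atp6 -0.20) and complement genes 0.26 (percentile 99.1; C3 1.35-fold, Serping1 1.20-fold). Hypoxia genes had a median of -0.51 (percentile 0.35; Gapdh -0.51, Ldha -0.32), which was 0.030 in thinned cells. Interferon response genes had 0.28 (percentile 98.5), although the abundant members Ifitm3 and B2m had -0.25 and -0.80, and the median was -0.044 at Leiden resolution 2 and -0.16 when near ties were named by markers found. Epithelial junction genes had -0.70 (percentile 0.54; Tjp1 -0.11), which turned to 0.76 in thinned cells. The lists inside the central range were immediate early genes (-0.33, percentile 45.8; Fos -0.16, Jun 0.26), extracellular matrix (-0.17, 84.9; Sparc -0.39, Col3a1 0.05), proteases (-0.22, 55.6; Timp1 -0.21, Ctsl 0.38), chemokines (-0.13, 61.2; Ccl7 -0.34, Cxcl1 -0.25), TGF-beta response (-0.24, 12.7; Pmepa1 -0.45) and mesenchymal transition (-0.23, 20.9; Sparc -0.39, Vim -0.82).

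Genes named as higher in KPC-4545 were Wfdc17 (27.2-fold, 18.2 to 41.4), the cartilage matrix gene Comp (20.0), the retinoic acid binding protein gene Crabp1 (9.44, 6.92 to 12.8), mt-Atp8 (6.87, 6.33 to 7.46), Ecrg4 (7.36), Slc5a3 (7.14), Tnfsf8 (6.20) and the mitotic genes Knl1 (10.8) and Aspm (9.98). Of these mt-Atp8 is a leading gene of sub-cluster 9, of low UMI counts, which held 16 of the 48 KPC-4545 and 6 of the 564 KPC-3403 cells. Lower genes, by inverse fold, were Calca (46.6, 15.9 to 226), Serpinb2 (44.1, 12.2 to 364), Cxcl13 (33.6, 11.5 to 163), Dlk1 (53.0, 9.48 to 2095), Slpi (13.4, 8.27 to 23.6) and Cd74, and, with 0 UMIs in KPC-4545 against a floor of 3 UMIs in that library, Cfd (at least 14.8-fold lower, exact lower limit 12.0), Cxadr (at least 13.6, limit 11.0), H2-Aa (at least 10.1, limit 8.19) and Calcb (at least 9.09, limit 7.36). Cxcl13, Calca and Serpinb2 are among the leading genes of the unnamed stromal cluster of the enriched KPC-3403 library. The Cxcl13 difference turned to 5.27 after free RNA was subtracted, at shares that are probably too high. In the fit of 3 libraries without a preparation term, edgeR called 0 genes for the line (543 at an unadjusted p under 0.05, 7 with DESeq2, 103 without a filter, 10 with all 4 libraries and the replicate block). By camera, MHC class II (adjusted p = 5.6e-12), heat shock (4.4e-07), hypoxia (5.8e-06), proliferation (1.1e-05) and epithelial junction genes (0.0122) stood apart, each with adjusted p = 0.634 with an estimated correlation. For proteases the median was 0.06, the mean -0.49 and camera's direction down. The fit of 3 libraries has 1 KPC-4545 library, which is assumed to vary like those of KPC-3403. In the fit of all 4 libraries the replicate block is the line itself, tested beside a preparation term, and the whole KPC-4545 library adds 3 fibroblast-like cells.

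The last comparison was of epithelial or tumour-like cells that stayed in the enriched libraries with those of the whole suspension. Those in the enriched libraries held little Epcam: 0.0190 and 0.291 UMIs per 10000 in KPC-4545 and KPC-3403, against 3.01 and 3.28 in the whole libraries. They held the intermediate filament gene Vim at 68.6 and 62.8 UMIs per 10000, against 30.9 and 34.7. The comparison covers named clusters only. It leaves out unnamed clusters 16 and 25, with 85 and 55 cells of the whole KPC-3403 library. Over all their cells, these clusters held Epcam at 9.15 and 7.62 UMIs per 10000. It also leaves out the unnamed clusters nearest to epithelial cells in the enriched KPC-4545 library, 64.0% of its cells. The signs and counts of list members below are of the fit over both lines. Of 18 epithelial junction and keratin genes 0 were higher, with 6 lower adjusted over the list alone and 0 over all genes (Krt8 log2 -0.77, Krt18 -0.40; camera adjusted p = 3.1e-22, and adjusted p = 0.586 with an estimated correlation). In each line taken alone 1 of 18 was higher. This list holds Epcam (-5.36), on which the cells were sorted, so part of its difference is set by the gate. The other 17 had a median of -1.76 (camera adjusted p = 1.3e-19, and adjusted p = 0.586 with an estimated correlation). Leaving out Epcam does not free the list of the gate, since genes expressed along with Epcam can be selected by it too. All 22 immediate early genes were higher, 16 adjusted over the list alone and 0 over all genes (Fos 1.29, Junb 1.42; camera adjusted p = 4.2e-19, and adjusted p = 0.586 with an estimated correlation), and 20 of 22 in KPC-4545 alone. All 13 heat shock genes were higher, 7 adjusted over the list alone and 0 over all genes (Hspa8 1.35, Hsp90ab1 0.31; camera adjusted p = 1.3e-13, and adjusted p = 0.586 with an estimated correlation), and 11 of 13 in KPC-3403 alone.

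In this class the edgeR fit with the line as a block tested 11818 genes and called 9, each with the same direction in both lines. The chemokine gene Ccl2 rose by 3.35 (SE 0.32, edgeR adjusted p = 0.0258) and Crabp2, a retinoic acid binding protein gene, by 3.75 (SE 0.38, adjusted p = 0.0306). Crabp1 rose as well (edgeR adjusted p = 0.0306), with 2688 and 183 UMIs in the enriched KPC-4545 and KPC-3403 libraries and 0 in both whole libraries. The trypsinogen gene Prss2 fell by 8.54 (SE 0.41, edgeR adjusted p = 0.002) and Sycn, of acinar granules, by 8.78 (adjusted p = 0.00976; 1 and 2 UMIs in the enriched KPC-4545 and KPC-3403 libraries, counting ratios 1143, 197 to 45901, and 209, 56.6 to 1752). So did Amy2a5 and Klk1, with Amy2a5 at 161 and 6 UMIs and Klk1 at 75 and 6 UMIs in the whole libraries and 0 in both enriched libraries (adjusted p = 0.0163 and 0.0242). Of the 12 acinar markers Prss2 alone passed in edgeR; Clps (log2 -8.70, adjusted p = 0.247) and Ctrb1 (-10.10, 0.57) did not. Hbb-bs fell by 7.05 (edgeR adjusted p = 0.00502) and Hba-a1 by 7.17 (adjusted p = 0.0163; 3 and 2 UMIs in the enriched libraries, counting ratios 85.4, 23.5 to 467, and 247, 67.0 to 2062). Outside cells, acinar markers made up 1.03% and 0.928% of UMIs in the whole libraries against 0.109% and 0.0143% in the enriched ones.

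Among the other lists in this class, 9 of 13 chemokine genes were higher and Ccl2 passed over all genes, with 7 higher and 1 lower adjusted over the list alone (Cxcl1 log2 1.56; adjusted p = 3.2e-07 by camera). Of 16 extracellular matrix genes 13 were higher, 3 adjusted over the list alone (Sparc 2.39, Fn1 -0.13; 2.4e-07), of 12 mesenchymal transition genes 10 (4; Vim 0.92, S100a4 1.12; 1.04e-05), of 10 proteases 9 (1; Timp1 1.14, Ctsl 0.47; 0.0325) and of 11 TGF-beta response genes 7 (3 higher and 1 lower; Inhba 1.46, Pmepa1 -0.31; 0.0344). The lines had unlike values in these lists, a difference that was not tested. In KPC-3403 alone 11 of 11 proteases (median 0.92) and 16 of 19 matrix genes (2.55) were higher, against 3 of 11 (-0.09) and 11 of 19 (0.20) in KPC-4545. Of 13 mitochondrially encoded genes 12 were lower, 5 lower and 1 higher adjusted over the list alone (mt-Co1 -0.76, mt-Atp6 -0.88; 1.2e-06). None of these 6 held by camera with an estimated correlation (adjusted p = 0.586 for chemokines, mesenchymal transition and TGF-beta response and adjusted p = 0.645 for the other 3). The proliferation (12 of 20 higher, adjusted p = 0.318), complement (2 of 7, 0.318), MHC class II (2 of 6, 0.126), hypoxia (5 of 15, 0.375) and interferon lists (11 of 22, 0.412) did not pass by camera, and 0 of their members passed by edgeR. The interferon median was -0.01, its mean 0.13 and camera's direction up.

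Different clusters held this class in the 4 libraries: clusters 7 (263 cells), 14 (138) and 8 (68) in enriched KPC-4545, clusters 8 (28) and 7 (13) in whole KPC-4545, clusters 1 (412) and 9 (187) in enriched KPC-3403, and clusters 8 (100), 9 (47) and 1 (34) in whole KPC-3403. The 9 calls became 0 without the line block (287 genes at an unadjusted p under 0.05) and 0 in cluster 8 alone (113 at that p). With a library left out, which drops the line block too, they became 0 (either whole library), 32 (enriched KPC-4545) and 616 (enriched KPC-3403). DESeq2 called 166. Without the enriched KPC-4545 library and the line term, the log2 values of Crabp2 and Ccl2 turned to -1.03 and -0.96, because the remaining enriched library is of the line with the lower level.

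RNA outside cells differed between the preparations. In barcodes with at most 100 UMIs, erythroid marker genes such as Hbb-bs made up 7.60% and 7.26% of UMIs in the whole KPC-4545 and KPC-3403 libraries and 0.706% and 0.0618% in the enriched ones. Fibroblast markers made up 0.397% and 0.223% in the whole libraries and 0.242% and 1.02% in the enriched ones, and epithelial markers 0.277% and 0.452% against 0.216% and 0.121%.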

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

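All tests of explanations in this part were chosen after the result was seen. Several values stood out because the lines went opposite ways between enriched and whole; these differences between lines were not tested. Mesothelial-like cells differed by 12.1 percentage points in KPC-3403 and -0.453 in KPC-4545. Among fibroblast-like cells, the antigen-presenting-like share differed by -8.54 percentage points in KPC-3403 and 4.17 in KPC-4545, and the unnamed state by 8.36 and -29.2, where the whole KPC-4545 library has 3 cells. In epithelial or tumour-like cells the list medians (log2, KPC-3403 then KPC-4545) were 0.55 and -2.11 for MHC class II, -0.25 and 0.32 for interferon response, 0.77 and -0.16 for TGF-beta response, 0.26 and -0.58 for hypoxia and glycolysis, and -0.58 and 1.05 for proliferation. Barcodes left out of the analysis also carried signal: of those with 500 UMIs, 50.5% (enriched KPC-4545), 3.18% (whole KPC-4545), 16.2% (enriched KPC-3403) and 3.22% (whole KPC-3403) exceeded the mitochondrial limit. Haemoglobin made up most UMIs of 332 barcodes in the whole KPC-4545 and 716 in the whole KPC-3403 library.

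Cells with little collagen and almost no Xist, the transcript of the inactive X chromosome, fill the enriched KPC-4545 library. Xist stood at 0.0190 UMIs per 10000 in the epithelial or tumour-like cells and 0.00611 in the unnamed clusters against 6.41 in fibroblast-like cells, which argues against fibroblasts that lost their markers. Broken cells or empty droplets are argued against by median UMIs of 42984 in the named cells and 26157 in unnamed cluster 2, against 7402.5 in fibroblast-like cells. By UMIs alone they may make up cluster 4 (672.5, with 0.269% mitochondrial UMIs), and stay open for clusters 3 (5089, 13.9%) and 20 (8534, 14.2%). Cluster 4 held Hbb-bs at 0.742 UMIs per 10000 over all libraries, against 39.5 in the free RNA of the enriched KPC-4545 library. Tumour cells that escaped the EPCAM gate were not settled by a test of 117 genes that set the lines apart in the whole libraries. Of these, 74.4% (65.5 to 82.0) lay on the KPC-4545 side in the named and 76.1% (67.3 to 83.5) in the unnamed cells. In the named cells, 39 of the 66 genes higher in KPC-4545 and 48 of the lower ones did. The higher ones included Amy2a5 and Klk1, with 0 UMIs in the named cells of both enriched libraries, so depth alone set their side. The test therefore cannot decide. By Xist, the collagen-poor cells resembled the epithelial or tumour-like cells of the whole KPC-4545 library (0 UMIs, exact limit 0.0394 per 10000). Its T-like and B or plasma-like cells held 5.42 and 5.58 per 10000, which argues against an origin from such Xist-bearing cells. Unnamed clusters 2, 3, 4 and 20 held 0 Epcam UMIs over all libraries. Cdkn2a was found in 99.1%, 73.5%, 51.8% and 78.8% of their cells, against 5% to 23.7% in the fibroblast-like clusters. Epcam RNA is not the protein that the gate reads, and how the collagen-poor cells passed it was not tested. The line itself stays open as untested.

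Immediate early and heat shock genes were higher in the enriched libraries. In the epithelial or tumour-like cluster that every library holds, the immediate early median was 0.78 in KPC-3403 and 0.58 in KPC-4545, which argues against a different mix of clusters as its whole cause, but its heat shock part cannot be told apart from such a mix, with medians of 0.29 (9 of 13 genes higher) and 0.10 (7 of 13). At its estimated share of 9.60% of UMIs, free RNA brings 32.6% of the difference of the summed lists in KPC-3403 fibroblast-like cells. Of the 737 marker UMIs behind that share, 507 were neutrophil markers. Erythroid markers made up 0.000531% of UMIs in these enriched cells, against 0.0618% in that library's free RNA. The share, and with it the 32.6%, is therefore probably too high. Free RNA stays open for the part it brings. After its subtraction at that share the medians were 0.51 for immediate early and 1.03 for heat shock genes, so it is not the whole cause. Handling during the sort cannot be told apart from the preparation itself: the immediate early median was above 0 in 100% of 6 pairs of a class and a line, but 5 of them share 1 pair of libraries (KPC-3403), and neutrophil-like cells there had a heat shock median of -0.43. The endothelial-like and erythroid-like pairs also set different kinds of cells side by side, by the Pecam1 and cluster values given above. No biological explanation was tested.

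MHC class II transcripts stood out in the unnamed stromal cluster of the enriched KPC-3403 library. Free RNA is argued against by Cd74 at 26.4 UMIs per 10000, 10.6-fold (10.2 to 11.0) the level in epithelial or tumour-like cells of that library. Doublets with immune cells are argued against by Ptprc, whose 2 UMIs are 0.733% (0.0888 to 2.65) of the 273 that this much Cd74 would bring from dendritic-like cells. The tumour line stays open as untested. Mesothelial-like cells of the enriched KPC-3403 library held Cd74 nearly as high, by the values given below, so it is not particular to the unnamed cluster.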

How the results depend on the processing

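Alternatives on naming, doublet rule, multinomial test, shared cluster, all 4 fibroblast libraries, collagen-expressing clusters together, list medians and named genes in fibroblasts, epithelial gene lists (with the list without Epcam), epithelial fits without a filter or under other cell settings, the leave-outs of depth, and the leave-outs and missing line term in the sums over all cells were chosen after seeing the data, the others before. The fibroblast share kept its direction in 15 of 15 alternatives, other class shares in 147 of 149, states in 38 of 45, list medians in fibroblasts were the same in 141 of 196 (enriched against whole) and 148 of 196 (lines), and named fibroblast genes in 237 of 280 and 229 of 280. No share could pass its test, so this says nothing of significance. For the values below the cause was not tested. The other cell class shares, endothelial, differed by -0.381 percentage points with at least 1000 UMIs and 500 genes; the inflammatory one -1.67 at Leiden resolution 2; the antigen-presenting one 2.78 with at least 1000 UMIs and 500 genes, 2.59 and 0.684 at Leiden 0.5 and 2, and 0.921 with near ties named by the share of markers found. For genes per fibroblast at a fixed number of UMIs the difference was -34.5 at 2000 UMIs. For sort target genes and all others, 26 genes passed with RLE, 774 without a filter, 1611 with DESeq2, 32 with no replicate block and 0 to 2700 leaving out 1 library together with the line term. In epithelial or tumour-like cells, 0 passed with no replicate block, 166 with DESeq2, 380 without a filter, 0 in the shared cluster, 18 at 10% mitochondrial, 24 with the UMI and gene minimum alone, 3 at Leiden 0.5, 36 with the automatic doublet threshold, 14 with the multinomial and 0 to 616 leaving out 1 library together with the line term. In fibroblasts, enriched against whole, 29 passed with DESeq2, 12 thinned, 31 with the replicate block over all 4 libraries, 62 at Leiden 2 and 70 with near ties. For the lines, 103 passed without a filter, 7 with DESeq2, 1 thinned, 10 with the replicate block over all 4 libraries, 38 with at least 1000 UMIs and 500 genes, 11 at 10% mitochondrial, 1 with the UMI and gene minimum alone, 2 at Leiden 0.5, 36 at Leiden 2, and 1 each with the automatic doublet threshold and the multinomial. In the comparison of lines the replicate block is the line term itself, beside a preparation term. The block changed no other call. With an estimated correlation and with fry, 0 lists passed in either fibroblast comparison and in epithelial cells. The version with an estimated correlation rests on 1 residual degree of freedom and could hardly pass any list. Erythroid markers were 7.97% of free RNA in the whole libraries at 50 UMIs. Medians in fibroblasts, enriched against whole, were -0.69 (MHC class II, equal cells), -0.17 (MHC class II, free RNA subtracted), -0.60 (proliferation, thinned) and -1.40 (proliferation, equal cells), with fibroblasts, enriched against whole, Cxcl13 at -3.45 (free RNA subtracted) and Krt7 at 2.32 (at least 1000 UMIs and 500 genes). For the lines they were -0.044 (interferon response, Leiden 2), -0.16 (interferon response, near ties), 0.030 (hypoxia and glycolysis, thinned), -0.24 (proliferation, near ties), 0.76 (epithelial junction and keratin, thinned) and 2.0 (the same list, free RNA subtracted), with Cxcl13 at 5.27 (free RNA subtracted). The free RNA shares subtracted from the enriched libraries are probably too high, by the erythroid marker values given above. Leaving out 1 library gave ranges of -0.135 (without enriched KPC-3403) to 62.6 (without enriched KPC-4545) percentage points for collagen-expressing clusters together, -0.298 to 11.9 for mesothelial, -16.5 to 12.1 for antigen-presenting, 20.5 to 44.3 for inflammatory, -31.8 to -7.95 for myofibroblastic, -33.5 to -11.1 for B or plasma cells, -12.0 to -4.75 for neutrophils, -3211 to 1739 UMIs for depth, and, with the line term dropped as well, log2 values of 1.99 to 12.65 for Apod in all cells and -1.03 to 8.29 for Crabp2 and -0.96 to 7.92 for Ccl2 in epithelial cells. Further leave-outs of the fibroblast fits were not run, as no residual degree of freedom is left, nor was the epithelial fit under naming by the best class of any, with under 20 cells in 2 libraries. Few cells limit the whole KPC-4545 library most, with 527 cells.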

Other observations

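All tests in this part were chosen after the data were seen. The lines were also compared in epithelial or tumour-like cells over both preparations. Cells of KPC-4545 held more of the chemokine genes Cxcl1 (log2 7.79, adjusted p = 0.00105) and Ccl2 (5.38, 0.00278), the tight junction gene Cldn18 (8.09), Mgp (6.48) and Crabp2 (5.94), and less of Saa3, an acute-phase gene (-9.60, 0.00499), Lcn2 (-9.18), Bmp2 (-8.88), Xist (-8.45) and Tm4sf4 (-7.33). Amdhd2 (8.87), Rangrf (7.70), Amigo2 (7.18), Hspb8 (5.69) and C1qtnf12 (5.26) were also higher, and Crisp1 (-8.89), Lepr (-7.34), Clec2f (-6.81) and Il5ra (-6.74) lower. Fitted values depend on the prior count where the lower line has few UMIs (enriched, then whole library): Amdhd2 1 and 0, Cldn18 0 and 3, Rangrf 2 and 0, Saa3 1 and 0, Lcn2 3 and 0, Bmp2 3 and 1, Lepr 1 and 1, Il5ra 3 and 0. For Saa3 the exact lower limit of the counting ratio was 178 in the enriched and 0.538 in the whole libraries, so the whole libraries alone do not set it apart. In all, edgeR called 147 of 11818 genes, 68 higher and 79 lower. Among list members, Ccl7 (3.74), Timp1 (2.79), Sparc (2.62) and Tgfbi (2.41) rose and H2-Eb1 (-3.88), C3 (-3.83) and Adm (-3.71) were lower. By camera the hypoxia (1 of 15 higher, adjusted p = 6.4e-07), epithelial junction (2 of 18, 6.9e-06), MHC class II (0 of 6, 1.1e-05), complement (0 of 7, 7.2e-05) and chemokine lists (9 of 13, 8.1e-06) stood apart, each with adjusted p = 0.689 with an estimated correlation. So did the mesenchymal transition (9 of 12, camera adjusted p = 0.00301), proliferation (19 of 20, 0.00509), heat shock (12 of 13, 0.00826), TGF-beta response (1 of 11, 0.0107) and immediate early lists (6 of 22, 0.019), with adjusted p = 0.689 to 0.834 with an estimated correlation, while the other 4 lists did not.

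The unnamed stromal cluster of the enriched KPC-3403 library held Col1a1 at 21.7 UMIs per 10000 (fibroblast-like cells 106, mesothelial-like cells 21.9), Pdgfra at 3.94 (2.01 and 1.47), Saa3 at 109.8 (19.6 and 42.9), Slpi at 38.9 (3.89 and 51.7) and Wt1 at 2.25 (0.846 and 2.10). Cd74 stood at 26.4 (3.33 and 20.9, and 245 in dendritic-like cells). Msln and Upk3b, mesothelial surface genes, stood at 0.105 and 0.403 against 1.95 and 2.83 in mesothelial-like cells. These genes were chosen after their values were seen.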
